A study of Mus musculus with 6 samples.

How the data were processed

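Total RNA of epidermal sheets from mouse embryos at embryonic day 18.5 was labelled with biotin and measured on expression arrays, 3 from Rptor cKO embryos and 3 from wild-type littermates, per the labels' protocols. The Ambion Expression WT kit was used, and RNA was prepared with TRIzol and RNeasy, per the labels' protocols. The deposited table holds log2 values per probe set, and the submitters' processing notes name RMA, Partek and the genome build mm10. The versions of these tools are not given in the sources used here. RMA as usually run subtracts background, makes the intensity distributions of arrays alike by quantile normalization and summarises the probes of a probe set by median polish. This forces arrays toward a common distribution, so that a general rise or fall of RNA per cell cannot be seen, and compresses changes of dim probe sets. The medians still differed a little between arrays, and the scale was taken as log2 because the values ran from 1.34 to 14.04. Each column was matched to its sample by name, so the direction of every difference is known. Slide, scan date and detection flags are not given in the sources used here, so array batches could not be tested. The 5222 negative control probe sets had a median from 3.81 to 4.11 on the arrays and a 95 percentile from 7.46 to 8.07. This spread sets no sharp limit of detection, so no probe set was judged absent, and the median served as a guide, chosen after the values were seen. Of 2886 changed genes, 131 lay under it on every array of a group, 38 of them on all 6 arrays. A fold given as at least a value was computed with each array's values raised to that median.

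Probe sets were named through a table of the platform's annotation, with symbols updated by Entrez ID. Of 72688 probe sets, 6732 were controls and were left out, 30604 named a single gene, 2146 several and 33206 none. An Entrez ID matched 22818 probe sets, and 1135 symbols were updated. The 30604 probe sets gave 30063 genes, and for 429 genes with several probe sets the one with the highest mean over all 6 arrays was used. Probe sets naming several genes were not given a gene, which left out some list members, among them Ctsd and Glb1 of the lysosome, and Krt6a and Krt6b. Coordinates are those of mm10.

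Differences were fitted on the log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the sole term and all 6 arrays, two-sided, and Benjamini-Hochberg adjustment over 30063 genes with a threshold of 0.05. The moderation had 4.31 prior degrees of freedom. No filter was set on dim probe sets. SE is the moderated standard error, and SD is over the 3 arrays of a group. A single gene compared without moderation by permutation could not go below p = 0.1 with 3 against 3 arrays. Gene lists, 47 in all, were written from general knowledge. They cover the lysosome and its regulators, mTOR, AKT, EGFR and other signalling, epidermal layers, metabolism, cell states and markers of other cell types that an epidermal sheet can hold. They were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with fry, and with preranked enrichment by fgsea 1.28.0, each adjusted by Benjamini-Hochberg over the lists. A list given with an adjusted p for an estimated correlation was past the threshold by camera with the preset correlation, the main test. For the other lists the adjusted p of that main test is given. Adjustment over a list alone used the p-values of its own members. Some genes belong to several lists. Of the 47 lists, 1 signalling list is not reported here, although the counts of lists include it. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for the annotation and plots.

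The group assignment, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took Rptor, the 12 largest rises and 12 largest falls past the threshold with groups that did not overlap, the MiT/TFE members, Egfr, Erbb2 and Erbb3, and from each described list up to 4 members with the smallest p in each direction that passed, or 2 where none passed. Predicted genes, RIKEN clones, microRNA, small RNA and olfactory or vomeronasal receptors were left out of the 12. Genes outside this rule are said to be so where they are named. Xist and Y-linked genes were used only to read the sex of the embryos.

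The procedure was tested on simulated data, with 30063 genes drawn with the means and spreads of the comparison of Rptor cKO with wild type and known changes added, 5 draws. It recovered 24.4% of genes changed by 0.5 on the log2 scale, 94.4% at 1 and 98.4% at 1.5 and at 2. Of 851 calls 61 were false, 7.17%. A list of 60 genes shifted by -0.3 was called in 5 of 5 draws by each of the 4 set tests, and none of 200 unshifted lists was. The simulated genes were independent of each other, so this says nothing about correlated lists. Fewer genes were changed than were called on the real arrays, which makes the adjusted threshold stricter, so the recovered shares do not carry over to them.

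Alternatives covered quantile normalization, subtraction of array medians, a filter on mean level, a floor at the 25 percentile of each array, the mean of a gene's probe sets, other variance moderation, array weights, each array left out in turn and the other set tests. Genes counted as higher or lower in a fit with fewer arrays are those past its threshold. Fewer arrays lower the power, so a smaller count need not mean a smaller change. Embryo sex as a term, the male arrays alone, and removal of X and Y genes were added after the sexes were seen.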

Results

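RNA of mouse epidermis was measured on 6 expression arrays. The tissue came from embryos late in gestation, when the skin barrier has formed. Epidermal sheets were separated from the dermis with ammonium thiocyanate, which leaves the dermis and its fibroblasts behind as far as the separation succeeds. The 3 Rptor cKO arrays came from conditional knockout embryos for Rptor, which encodes Raptor, the subunit that brings substrates to the kinase complex mTORC1. The 3 wild-type arrays came from littermates, and the series description calls the samples of each group biological replicates. All differences below are Rptor cKO minus wild type on the log2 scale. The title and design of the series ask whether lysosomal genes are lower without Raptor, and name AKT feedback, the MiT/TFE transcription factors and EGFR degradation as the subject.

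The median log2 value over all probe sets was 4.22, 4.22 and 4.15 in Rptor cKO arrays 1 to 3 and 4.16, 4.14 and 4.08 in wild-type arrays 4 to 6. The mean correlation of an array across genes was 0.989 to 0.992 with arrays of its own group and 0.966 to 0.982 with the other group. The first principal component held 72.3% of the variance and separated the groups, with Rptor cKO arrays at 38.3, 39.3 and 17.8 and wild-type arrays at -44.9, -23.6 and -26.8. Xist, the RNA of the inactive X chromosome, read 10.57 or more in Rptor cKO arrays 1 and 3, and 3.55 in Rptor cKO array 2. It lay between 3.23 and 3.40 in the wild-type arrays. By Xist and the Y-linked genes the Rptor cKO group held 2 females and 1 male, and the wild-type group 3 males. The number of arrays limits the precision of every value below.

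Rptor itself (chromosome 11, 119602905 to 119899591, mm10) read 6.69 ± 0.14 in Rptor cKO and 7.15 ± 0.27 in wild type (SD, n = 3), a difference of -0.46 (SE 0.15). The 3 Rptor cKO arrays all lay below the 3 wild-type arrays, but the difference missed the threshold after Benjamini-Hochberg adjustment in limma (adjusted p = 0.0988). The probe set value covers the gene as a whole, and which exons were deleted is not given in the sources used here, so the value is a weak check of the genotype labels.

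Among the largest falls were Skint9, of a family of keratinocyte surface proteins, and Hal, the histidine ammonia-lyase of the cornified layer. Skint9 read 3.36 ± 1.17 in Rptor cKO against 8.60 ± 0.45 in wild type, and Hal 5.33 ± 1.57 against 10.41 ± 0.50 (SD, n = 3 each). Skint9 lay under the median of the negative control probe sets on Rptor cKO arrays 1 and 2, and with values raised to that median it fell at least 20.8-fold (measured -5.24, SE 0.51, adjusted p = 0.00152). Hal fell 33.7-fold (-5.08, SE 0.66, adjusted p = 0.00427). Casp14, the protease that acts on filaggrin, fell 14.6-fold (-3.87, SE 0.51, adjusted p = 0.00428). Npl, Tmprss11f, Atp13a4, Skint6, Il1f8 (interleukin 36 beta), Serpinb12, Them5, Slc46a2 and Fads2b completed the 12 largest falls by measured value, with log2 changes from -4.13 for Npl to -3.27 for Fads2b. Of these, Skint6 lay under that median on all 3 Rptor cKO arrays and Tmprss11f and Il1f8 on 2. Among the largest rises was Nrg1, the neuregulin ligand of ERBB3 and ERBB4, at 6.25 ± 0.15 in Rptor cKO against 3.77 ± 0.055 in wild type (SD, n = 3). The wild-type arrays lay under the same median, so that the rise was at least 5.31-fold (measured 2.49, SE 0.10, adjusted p = 9.04e-05). Tnc, an extracellular matrix protein of healing skin, rose 5.51-fold (2.46, SE 0.23), Dusp6, a phosphatase of ERK, rose 5.40-fold (2.43, SE 0.23) and Krt16, a keratin of injured and hyperproliferative epidermis, rose 4.75-fold (2.25, SE 0.29). Ccl20, Wif1, Plet1, Ccn1, Lgals1, Ndn, Pdpn and Upk1b completed the 12 largest rises by measured value, from 2.24 for Ccl20 to 1.75 for Upk1b.

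Of 30063 genes tested, 1095 were higher and 1791 lower in Rptor cKO, 2886 in all, so that 62.1% of the changed genes were lower. By 2-fold or more, 125 genes rose and 713 fell, and by 4-fold or more 11 rose and 163 fell. The groups did not overlap for 8709 genes, 29.0% of those tested, where chance gives 10%. With each array's median subtracted, 75.7% of 2428 changed genes were lower. The count was 900 without Rptor cKO array 2, the male of that group, and 1854 without Rptor cKO array 1. It was 8 with an ordinary linear model without variance moderation. The fits with the male arrays alone and with embryo sex as an added term both compare Rptor cKO array 2 alone with the wild type. All 2886 genes kept their direction with any 1 array left out. This outcome was fixed in advance, since the groups overlapped for none of the 2886 genes, which were chosen on the same arrays.

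**Figure D1:**
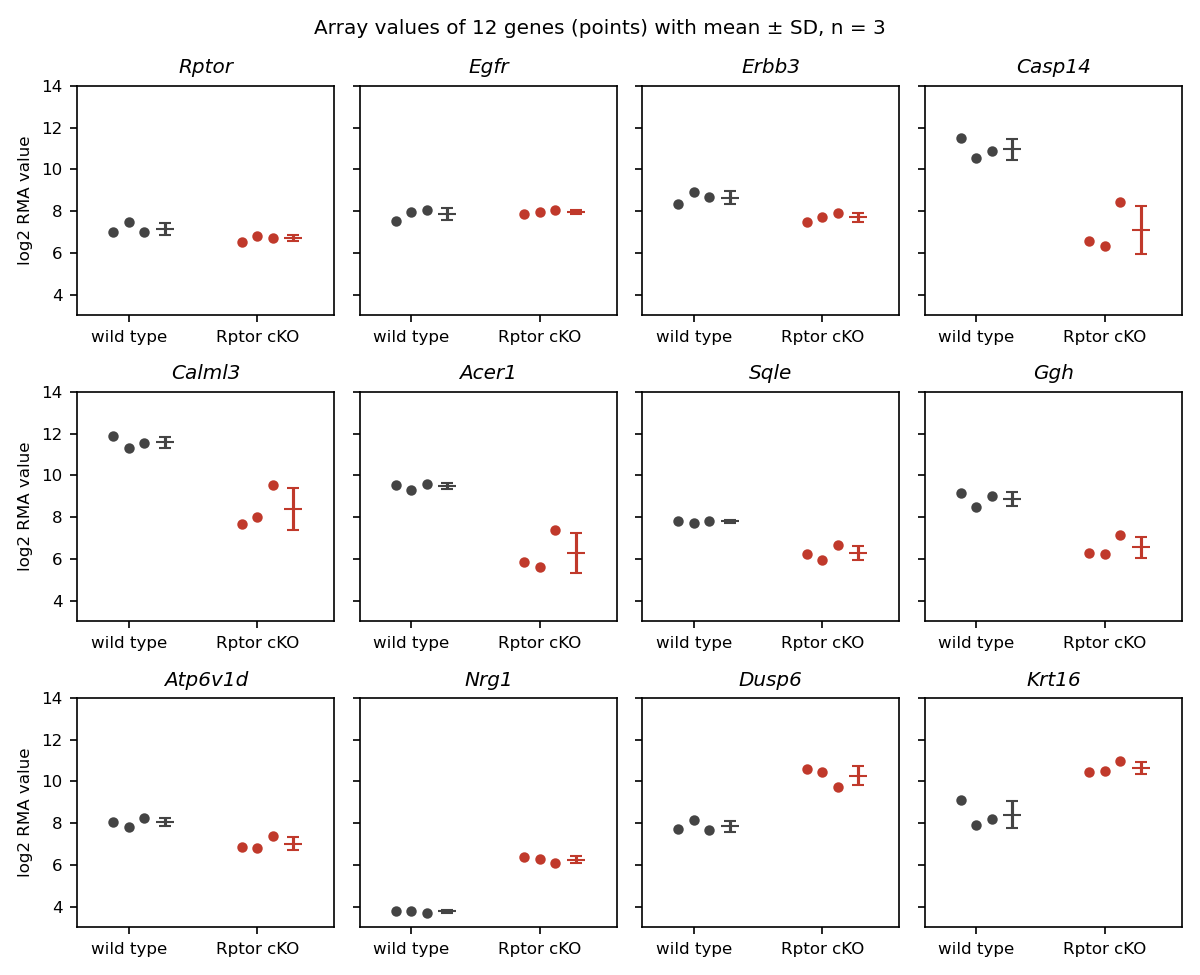
Log2 RMA value (vertical axis) of 12 genes on each array, with points for the 3 wild-type and 3 Rptor cKO arrays and a bar for mean ± SD beside them. Nrg1, Dusp6 and Krt16 lie higher in every Rptor cKO array, Egfr overlaps between the groups, and in Casp14, Calml3 and Acer1 the Rptor cKO arrays spread more widely than the wild-type arrays.

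Lysosomal genes were lower as a group. In the list of 185 measured lysosomal genes, 48 fell, 2 rose and 135 did not pass the test, and adjusted over the list alone 75 fell and 5 rose. Among the hydrolases, Ggh (gamma-glutamyl hydrolase) read 6.56 ± 0.51 against 8.89 ± 0.34 (SD, n = 3), a 5.01-fold fall (-2.32, SE 0.26, adjusted p = 0.00235). Naaa, which cleaves N-acylethanolamines, fell by 1.54 (SE 0.12), and Fuca1, the lysosomal fucosidase, fell by 1.55 (SE 0.20). Lyst, a regulator of lysosome size, fell by 1.77 (SE 0.21), and Sort1, a sorting receptor, fell by 1.28 (SE 0.18). Igf2r, the receptor that carries mannose 6-phosphate tagged enzymes, rose by 0.51 (SE 0.10), and Cd63, a membrane protein of late endosomes, rose by 0.57 (SE 0.13). The rises numbered 0 without Rptor cKO array 1 or 2, 1 without Rptor cKO array 3, and 2 without wild-type array 4, 5 or 6. Chosen after their values were seen as widely used lysosomal markers, Psap (prosaposin) fell by 0.59 (SE 0.12, adjusted p = 0.0203), and Lamp1 differed by -0.19 (SE 0.10, adjusted p = 0.325). The median log2 change of the list was -0.24, and camera with a preset correlation placed the list below other genes (adjusted p = 4.35e-17), but with adjusted p = 0.206 with an estimated correlation. Preranked enrichment gave a normalized score of -2.81. In the fit without Rptor cKO array 2, 11 of these genes passed the test as lower, and without Rptor cKO array 1, 30. The medians there were -0.25 and -0.22, and with the male arrays alone -0.27.

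Each part of the lysosome list moved the same way. The 61 hydrolases and their cofactors held 19 falls and no rise (26 falls and 2 rises adjusted over the list alone; median -0.21; adjusted p = 0.225 with an estimated correlation). Of 52 membrane proteins, 8 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.17; adjusted p = 0.206 with an estimated correlation). Slc38a9, the lysosomal arginine sensor that acts on mTORC1, fell by 1.09 (SE 0.14). In the V-ATPase, the proton pump that acidifies the lysosome, 10 of 23 subunits and assembly genes fell and none rose, with a median of -0.54 (12 falls and 1 rise adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). These included Atp6v1c2 (-2.13, SE 0.36), Atp6v1d (-1.03, SE 0.17), Atp6v0e (-0.95, SE 0.15) and Atp6v1e1 (-0.92, SE 0.16). Of 49 genes of trafficking to the lysosome, 11 fell and 1 rose (20 and 1 adjusted over the list alone; median -0.27; adjusted p = 0.208 with an estimated correlation). With Rptor cKO array 2 left out, the falls numbered 5 hydrolases, 1 membrane protein, 2 V-ATPase genes and 3 trafficking genes. The panel of 360 genes that the series design names was not used here, and the list was written from general knowledge in its place.

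The RNA of the MiT/TFE factors, which switch on lysosomal genes, did not pass the test for any member: Mitf differed by 0.05 (SE 0.20), Tfeb by 0.00092 (SE 0.10), Tfe3 by -0.082 (SE 0.095) and Tfec by 0.17 (SE 0.10), with adjusted p from 0.367 to 0.999, and Tfec lay under the negative control median on all 6 arrays. Their activity is set largely by phosphorylation and location, which arrays do not measure. Of 24 MiT/TFE target genes, a list that leaves out the hydrolases, 4 fell and none rose (6 and 0 adjusted over the list alone). The 4 were Nupr1 (-1.05, SE 0.13), Gabarapl1 (-1.01, SE 0.18), Ulk1 (-0.73, SE 0.15) and Rragc (-0.47, SE 0.11). The camera call of that list (adjusted p = 0.0206) had adjusted p = 0.364 with an estimated correlation. Of 40 autophagy genes, 10 fell and none rose (20 and 0 adjusted over the list alone), with a median of -0.34 and adjusted p = 0.176 with an estimated correlation. Bnip3, a mitophagy receptor, fell by 1.73 (SE 0.14), and so did Gabarapl2 (-1.53, SE 0.30) and Atg13 of the ULK1 complex (-0.87, SE 0.12). Without Rptor cKO array 2, 2 autophagy genes and 1 target gene were lower, and without Rptor cKO array 1, 4 autophagy genes. The autophagy median was still -0.34 without Rptor cKO array 2, with 35 of 40 genes below 0.

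Genes of the mTOR, PI3K and AKT pathways moved in both directions. Of 43 genes of the mTOR complexes and their regulators, 10 fell and 2 rose (15 and 4 adjusted over the list alone; median -0.20; adjusted p = 0.206 with an estimated correlation). The stress regulators Sesn1 (-1.46, SE 0.15) and Sesn3 (-1.39, SE 0.20) fell, and Rps6kb2, an S6 kinase, fell by 0.85 (SE 0.15). The mTOR inhibitor Deptor rose by 1.10 (SE 0.21), and the insulin receptor adaptor Grb10 rose by 0.41 (SE 0.10). In the PI3K and AKT list of 34 genes, 3 rose and 3 fell (8 and 10 adjusted over the list alone), and camera did not call the list (adjusted p = 0.105). Igf1r rose by 0.83 (SE 0.12), Irs2 by 0.62 (SE 0.16) and Akt1 by 0.42 (SE 0.11), while Pik3r3 (-1.14, SE 0.12), Igfbp5 (-1.21, SE 0.27) and Foxo1 (-0.72, SE 0.18) fell. Among 26 FoxO target genes, 7 fell and 3 rose (9 and 4 adjusted over the list alone), with a median of -0.038 and adjusted p = 0.402 with an estimated correlation. Cat (catalase) fell by 1.67 (SE 0.17), and Ccn2 and Trib1 rose by 0.55 (SE 0.13) and 0.62 (SE 0.15). On the 5 arrays besides Rptor cKO array 2, the mTOR list held 2 falls and 1 rise, the PI3K and AKT list 1 fall and 1 rise, and the FoxO list 5 falls and no rise. The PI3K and AKT list held 6 rises and 2 falls without Rptor cKO array 1, and 1 rise and 4 falls without Rptor cKO array 3.

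The EGFR family list, of receptors, ligands and feedback genes, was mixed by role. Egfr read 7.96 ± 0.096 in Rptor cKO and 7.85 ± 0.28 in wild type (SD, n = 3), a difference of 0.11 (SE 0.14) within the replicate spread (limma adjusted p = 0.701). Erbb2 differed by -0.38 (SE 0.20, adjusted p = 0.311), and Erbb3 fell by 0.94 (SE 0.17, adjusted p = 0.0121). Among the ligands, Nrg1 rose as above, Epgn (epigen), under the negative control median on 2 of 3 wild-type arrays, rose at least 2.86-fold (measured 1.64, SE 0.18) and Btc (betacellulin) fell 7.52-fold (-2.91, SE 0.47, adjusted p = 0.00908). Adam17, the sheddase of EGFR ligands, fell by 0.48 (SE 0.12). The feedback genes Dusp6 and Spry4 rose by 2.43 (SE 0.23) and 0.93 (SE 0.10). In all 7 of 25 genes rose and 3 fell (8 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0968). It was past the threshold with array medians subtracted (adjusted p = 0.0201) and with quantile normalization (adjusted p = 0.0249). The same held with fry (adjusted p = 0.0217) and with preranked enrichment (adjusted p = 0.000522). Its adjusted p over all alternatives ran from 0.000522 to 0.374. In the fit without Rptor cKO array 2, 4 rose and 1 fell. EGFR protein and its degradation were not measured on these arrays.

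In the Notch list of 17 genes, which camera did not call (adjusted p = 0.277), 3 rose and 2 fell (4 and 2 adjusted over the list alone). The ligands Jag2 and Dll1 rose by 0.76 (SE 0.10) and 0.73 (SE 0.092), Notch1 rose by 0.45 (SE 0.11), and Notch2 (-0.64, SE 0.13) and Notch3 (-0.49, SE 0.12) fell. Both falls were lost in the fits without Rptor cKO array 2, without wild-type array 6 and with the male arrays alone, which held 2, 2 and 1 rises.

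The layers of the epidermis moved apart. Basal layer genes were higher, with 9 of 26 up and 1 down (13 and 2 adjusted over the list alone), a median of 0.41 and adjusted p = 0.316 with an estimated correlation. Lgals1, a galectin, read 9.87 ± 0.23 against 7.87 ± 0.074 (SD, n = 3), a 4.02-fold rise (2.01, SE 0.13). The integrins Itga3 and Itgb4, which anchor basal cells, rose by 1.41 (SE 0.16) and 0.98 (SE 0.11), Ccnd2 rose by 1.09 (SE 0.11), and Krt15 fell by 2.31 (SE 0.35). Spinous layer genes were lower, with 18 of 24 down and none up (20 and 0 adjusted over the list alone), a median of -1.20 and adjusted p = 0.225 with an estimated correlation. Calml3, a calmodulin-like protein of keratinocytes, fell 9.04-fold (-3.18, SE 0.43), and Dapl1 (-2.81, SE 0.39), Skint3 (-2.13, SE 0.26) and Krtdap (-1.97, SE 0.30) fell with it. Among 67 genes of the granular layer and cornified envelope, 34 fell and 2 rose (39 and 4 adjusted over the list alone), with a median of -1.12 and adjusted p = 0.354 with an estimated correlation. Tgm3, a crosslinking transglutaminase, fell 7.54-fold (-2.91, SE 0.26), as did Padi1 (-1.75, SE 0.19) and Tgm5 (-1.40, SE 0.17), whereas Klk10, a protease, rose by 1.33 (SE 0.11).

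Chosen after their values were seen as the usual keratins and envelope proteins of each layer, Krt5 and Krt14 of the basal layer differed by 0.035 (SE 0.14) and 0.26 (SE 0.12) and did not pass the test. Krt1 (-2.07, SE 0.39) and Krt10 (-1.76, SE 0.35) of the spinous layer fell. Filaggrin, Flg (-2.57, SE 0.61, adjusted p = 0.0356), and loricrin, Lor (-1.47, SE 0.35, adjusted p = 0.0349), fell as well. Flg read 9.34 ± 1.48 in Rptor cKO against 11.91 ± 0.31 in wild type (SD, n = 3), so its spread was wider between the Rptor cKO arrays. Without Rptor cKO array 2 the change of Flg was -2.58 (adjusted p = 0.122) and that of Lor -1.33 (adjusted p = 0.141). Over all alternatives Flg ran from -3.31 to -1.82 and lost its call in 10 of 17 (adjusted p 0.00312 to 0.243), and Lor ran from -1.75 to -1.08 and lost its call in 8 of 17 (adjusted p 0.0210 to 0.237). In that setting 4 basal genes were higher, and 10 spinous and 8 cornified genes were lower. Without Rptor cKO array 1, 19 cornified genes were lower.

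The genes that make the barrier lipids fell furthest of the 47 lists by their median, -1.53. Of 36 measured, 24 fell and none rose (28 falls and 2 rises adjusted over the list alone), with adjusted p = 0.208 with an estimated correlation. Acer1, the alkaline ceramidase of the epidermis, read 6.27 ± 0.96 against 9.49 ± 0.15 (SD, n = 3), a 9.33-fold fall (-3.22, SE 0.40, adjusted p = 0.00352). Abhd5, the cofactor of the lipase that supplies acylceramide, fell by 1.65 (SE 0.18). Cyp4f39, the omega-hydroxylase of ultra-long fatty acids, fell by 1.53 (SE 0.20), and Sptlc1, of the enzyme that starts sphingolipid synthesis, fell by 1.34 (SE 0.17). Of 32 genes of desmosomes and tight junctions, 13 fell and 2 rose (16 and 4 adjusted over the list alone), with a median of -0.26 and adjusted p = 0.316 with an estimated correlation. Dsg1a and Dsg1b, desmogleins of upper layers and near copies of each other, fell (-2.15, SE 0.35, and -1.95, SE 0.31), and so did the tight junction genes Cldn1 (-1.16, SE 0.18) and Tjp3 (-1.11, SE 0.13). Dsg3 and Cdh3, adhesion genes of lower layers, rose by 0.70 (SE 0.17) and 0.72 (SE 0.18). On the 5 arrays besides Rptor cKO array 2, 11 barrier lipid genes and 5 adhesion genes were lower, and 0 adhesion genes were higher. The rises of adhesion genes also numbered 0 without Rptor cKO array 3, wild-type array 4 or wild-type array 5, and 2 without Rptor cKO array 1 or wild-type array 6.

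Stress and alarmin genes split, with 7 of 32 higher and 7 lower (10 and 9 adjusted over the list alone), and camera did not call the list (adjusted p = 0.597). Its median was 0.13 and its mean -0.075. Krt16, Ccl20 and Tnf (1.25, SE 0.25) rose, and Tslp, counted as higher, lay under the negative control median on all 6 arrays. Il1f8 fell at least 9.58-fold (measured -3.58, SE 0.64), and the cystatins Stfa3, Stfa1 and Stfa2, which are close paralogs that can share probes, fell (-1.63, SE 0.19; -1.23, SE 0.19; -2.34, SE 0.41). Of 44 hair follicle genes, 4 rose and 4 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.105). Wif1 and Dkk4, inhibitors of WNT, rose by 2.06 (SE 0.14) and 1.02 (SE 0.15), and Edar, the ectodysplasin receptor of hair placodes, rose by 1.08 (SE 0.14). In the fit without Rptor cKO array 2, 3 stress genes rose and 2 fell, and 4 hair follicle genes rose and none fell. The falls of hair follicle genes numbered 13 without wild-type array 4, 1 without wild-type array 6 and 0 with the male arrays alone.

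**Figure D2:**
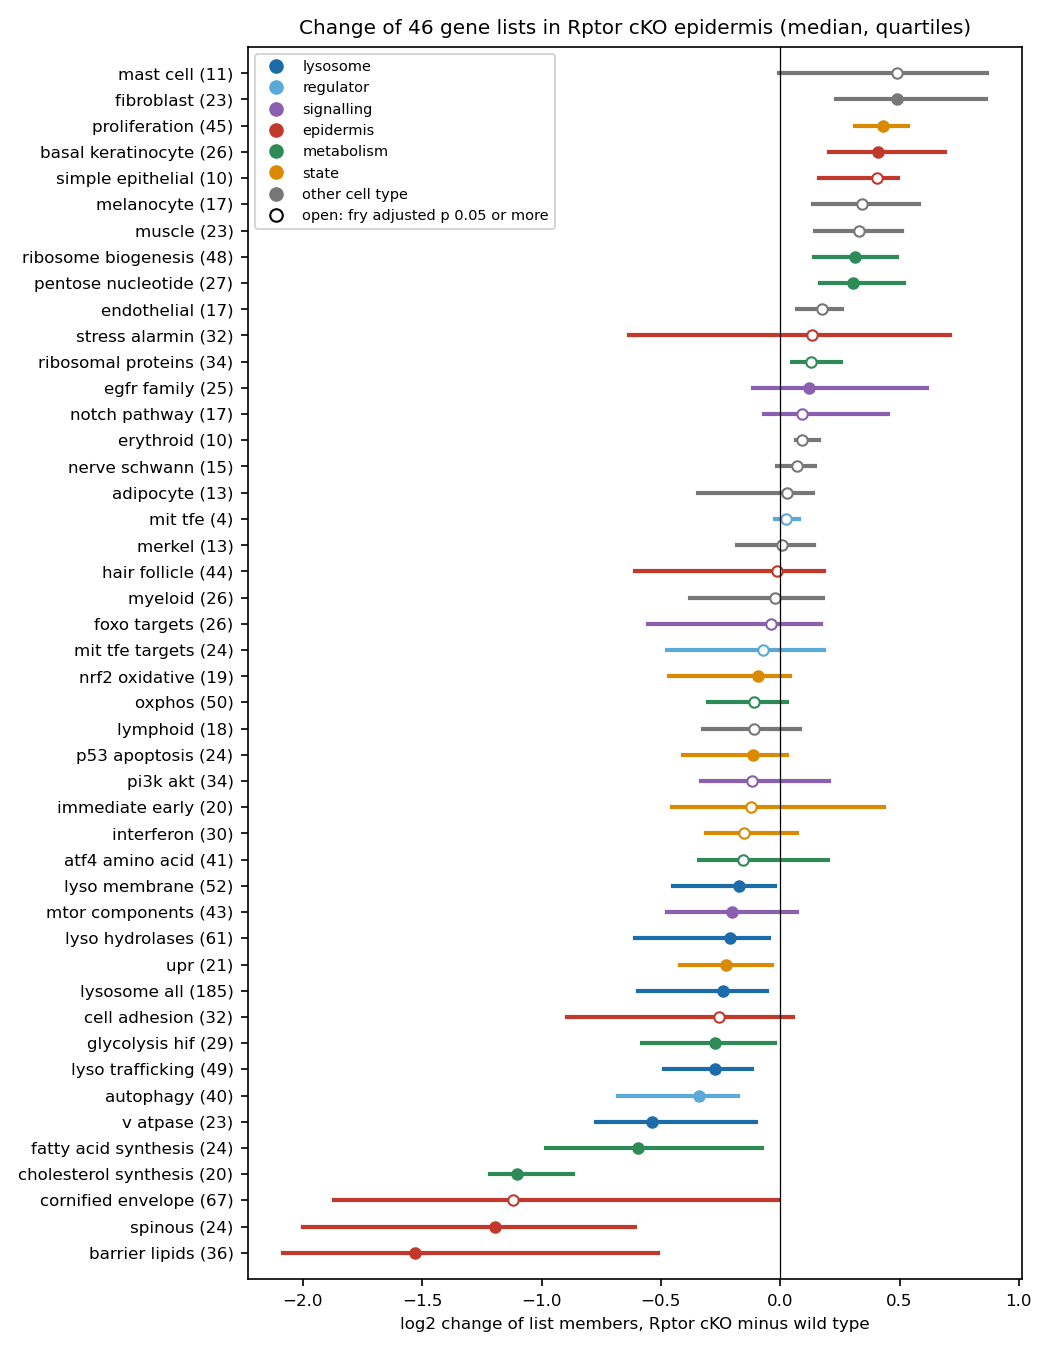
Log2 change, Rptor cKO minus wild type, of 46 gene lists (horizontal axis), with a point at the median of each list and a line over its quartiles; the number of measured genes is in brackets. Colours give the kind of list, and open points mark lists with a fry adjusted p of 0.05 or more. Barrier lipid (-1.53), spinous (-1.20), cornified (-1.12) and cholesterol (-1.10) genes have the lowest medians, and mast cell (0.49), fibroblast (0.49) and proliferation (0.43) genes the highest.

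Lipid synthesis genes were lower. mTORC1 activates such genes through SREBP factors, but whether their fall came from that or from a change in cell state was not tested. Of 20 cholesterol synthesis genes, 19 fell and none rose, with the same numbers adjusted over the list alone, a median of -1.10 and adjusted p = 0.206 with an estimated correlation. Stard4, a sterol carrier, read 4.84 ± 0.36 against 6.92 ± 0.18 (SD, n = 3), a 4.23-fold fall (-2.08, SE 0.18, adjusted p = 0.00109). Hsd17b7 (-1.80, SE 0.19), squalene epoxidase Sqle (-1.53, SE 0.16) and Hmgcs1 (-1.27, SE 0.14) also fell. Among 24 fatty acid synthesis genes, 12 fell and none rose (14 falls and 2 rises adjusted over the list alone), with a median of -0.59 and adjusted p = 0.206 with an estimated correlation. Acaca, the rate-limiting carboxylase, fell by 0.78 (SE 0.11), and Gpam (-1.19, SE 0.13) fell too. Elovl3 lay under the negative control median on all 3 Rptor cKO arrays and fell at least 2.02-fold (measured -1.61, SE 0.23). With Rptor cKO array 2 left out, 14 cholesterol and 9 fatty acid genes were lower.

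Glycolysis and hypoxia genes were lower in 11 of 29 and higher in 2, with the same numbers adjusted over the list alone, a median of -0.27 (-0.13 without wild-type array 5) and adjusted p = 0.225 with an estimated correlation. Egln3, an oxygen sensor, fell by 1.87 (SE 0.18), as did Aldoc (-1.42, SE 0.21) and Hk1 (-0.76, SE 0.11), while the glucose transporter Slc2a3 rose by 1.71 (SE 0.11). In the list of pentose phosphate and nucleotide synthesis genes, 9 of 27 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.31; adjusted p = 0.291 with an estimated correlation). The nucleotide synthesis genes Ppat, Tyms and Atic rose by 0.76 (SE 0.14), 0.57 (SE 0.091) and 0.57 (SE 0.11), and the pentose phosphate genes Pgd (-0.84, SE 0.12) and Taldo1 (-0.76, SE 0.14) fell. ATF4 and amino acid genes went both ways, with 5 of 41 up and 5 down (5 and 8 adjusted over the list alone; median -0.15; adjusted p = 0.208 with an estimated correlation). The amino acid transporters Slc7a1, Slc7a5 and Slc38a2 rose by 1.23 (SE 0.12), 1.04 (SE 0.21) and 0.98 (SE 0.13), and the stress genes Ddit4 (-1.04, SE 0.21) and Trib3 (-0.74, SE 0.16) fell. Without Rptor cKO array 2, 5 glycolysis genes were lower, 1 nucleotide gene was higher, and of the ATF4 list 2 rose and none fell.

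Ribosome biogenesis genes were higher in 13 of 48 and lower in none (19 and 0 adjusted over the list alone), with a median of 0.31 and adjusted p = 0.316 with an estimated correlation. Polr1b, of RNA polymerase I, rose by 0.78 (SE 0.13), Utp20 by 0.66 (SE 0.11) and Nat10 by 0.58 (SE 0.11). Of 34 measured ribosomal protein genes, 3 rose (0 adjusted over the list alone; median 0.13, or 0.063 without wild-type array 4; adjusted p = 0.515 with an estimated correlation), namely Rpl4 (0.37, SE 0.095), Rps18 (0.32, SE 0.082) and Rpl6 (0.36, SE 0.093). Cell cycle genes were higher in 17 of 45 and lower in none (28 and 0 adjusted over the list alone), with a median of 0.43 and adjusted p = 0.291 with an estimated correlation. Mcm3, of the replicative helicase, rose by 0.70 (SE 0.11), E2f1 by 0.67 (SE 0.11) and Tk1 by 0.55 (SE 0.094). On the 5 arrays besides Rptor cKO array 2, 2 ribosome biogenesis, 0 ribosomal protein and 4 cell cycle genes passed the test as higher. The medians there were 0.35, 0.12 and 0.42, with 42 of 48, 29 of 34 and 44 of 45 genes above 0. The male arrays alone, with 1 Rptor cKO array, gave medians of 0.25, 0.16 and 0.47.

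Fibroblast genes were higher in the Rptor cKO sheets, with 10 of 23 up and none down (15 and 0 adjusted over the list alone), a median of 0.49 and adjusted p = 0.231 with an estimated correlation. Dcn (decorin) read 8.78 ± 0.16 against 7.85 ± 0.074 (SD, n = 3), a 1.91-fold difference (0.94, SE 0.11), Sparc rose by 0.88 (SE 0.089), Fn1 by 0.84 (SE 0.11) and Col5a1 by 0.67 (SE 0.10). Of the Rptor cKO arrays, array 3 lay nearest the wild type in the mean of the fibroblast genes, as in those of lysosomal, differentiation and cholesterol genes. In the fit without Rptor cKO array 2, 4 fibroblast genes were higher. Endothelial genes were higher in 3 of 17 (3 adjusted over the list alone; median 0.17, or 0.26 without wild-type array 4; adjusted p = 0.515 with an estimated correlation), with Pecam1 at 0.53 (SE 0.10) and Flt1 at 0.74 (SE 0.14). Skeletal and smooth muscle genes had a median of 0.33 with 1 of 23 higher, Tpm2 (1.08, SE 0.16), and adjusted p = 0.495 with an estimated correlation. With Rptor cKO array 2 left out, 0 endothelial genes and 1 muscle gene were higher, and without wild-type array 6, 0 and 1, while without Rptor cKO array 3, 2 and 5 were, and without wild-type array 4, 2 and 3. Of 26 myeloid genes 5 fell (5 falls and 1 rise adjusted over the list alone; median -0.021; camera adjusted p = 0.0948), among them Itgam (-0.76, SE 0.12) and Csf1r (-0.64, SE 0.12). There were 3 falls without Rptor cKO array 2, and with the male arrays alone none fell and 1 rose. The myeloid median turned to 0.19 with the male arrays alone, to 0.095 without Rptor cKO array 1 and to 0.11 without wild-type array 5.

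**Figure D3:**
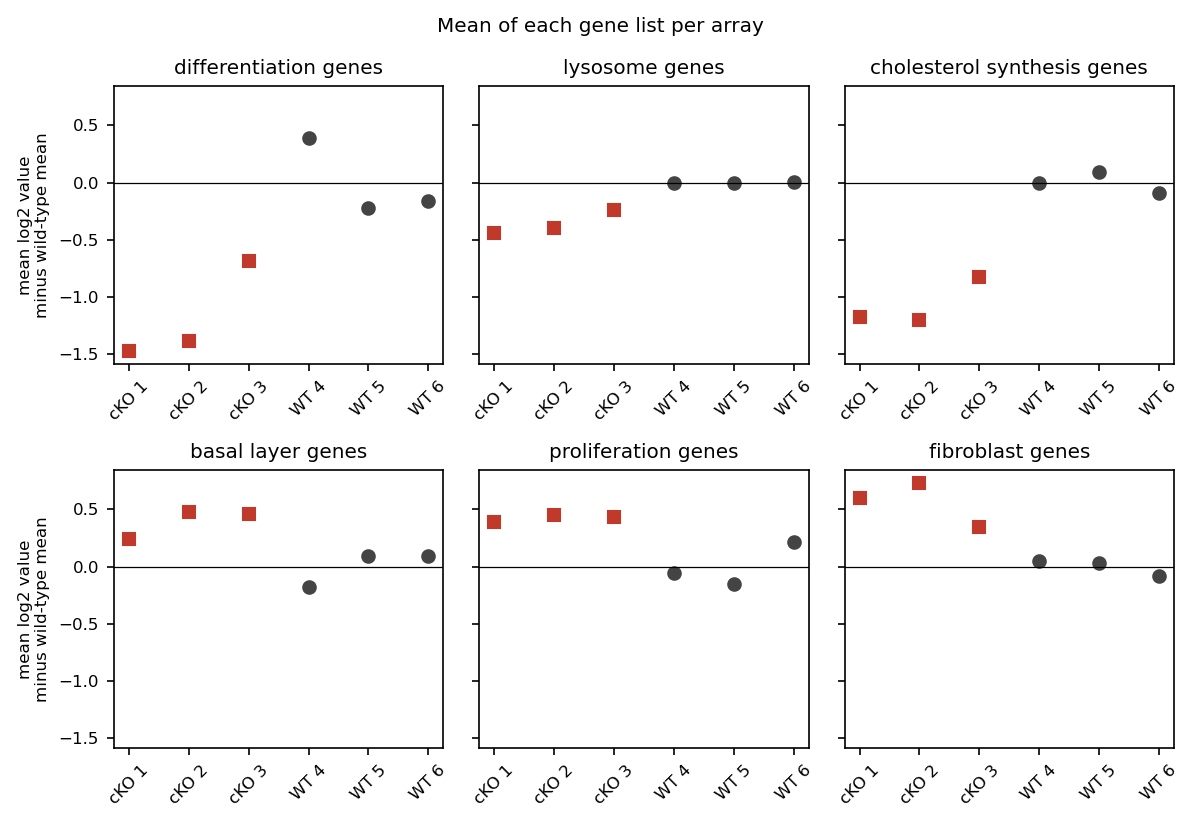
Mean log2 value of 6 gene lists on each array, minus the wild-type mean (vertical axis), with squares for Rptor cKO and circles for wild-type arrays. In all 6 panels the 3 Rptor cKO arrays lie on the same side of every wild-type array, and Rptor cKO array 3 lies nearest to wild type in the differentiation, lysosome, cholesterol and fibroblast panels.

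By camera with the preset correlation, the main test, 33 of the 47 lists were past the threshold, 10 upward and 23 downward. Their camera adjusted p ran from 1.77e-21 for the cholesterol list to 0.0300 for the ATF4 list. With an estimated correlation 0 were, fry placed 21 past the threshold and preranked enrichment 35. The fry p tests whether the genes of a list move, on balance, in 1 direction, and neither it nor the mixed fry p compares a list with other genes. The lysosome list had a fry adjusted p of 0.0224, and the barrier lipid, cholesterol, spinous, cell cycle and fibroblast lists had 0.0285, 0.0217, 0.0312, 0.0309 and 0.0224, while the cornified list had 0.117.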

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

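Of the tests in this part, those of basal layer genes and of markers of other dermal cell types were chosen after the result was seen, as were the counts of probe sets that name no single gene, the simulated arrays and the fits with a wild-type array kept for the male Rptor cKO array. Bootstrap intervals in this part resample genes and not arrays, so they do not measure the spread between embryos.

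Probe sets outside the gene table also differed between the groups. Of 2146 probe sets that name several genes, 47 were higher and 29 lower in Rptor cKO at a limma adjusted p under 0.05, 3.54% of them. Of 33206 that name no gene, 234 were higher and 178 lower, 1.24%. They are listed because no comparison above used them.

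The pattern of 2886 changed genes coincides with a sex difference, since all wild-type embryos were male and 2 of 3 Rptor cKO embryos were female. Of 900 genes called with the female Rptor cKO arrays alone, 900 went the same way in the male Rptor cKO array. Their median ratio to the change in the females was 1.13 (95% bootstrap interval 1.11 to 1.15). Simulated arrays with no change in the male gave 57.9% and a ratio of 0.057, from up to 4708 called genes. The simulated genes were independent, so real genes that move together could go the same way more often without such a change. With wild-type array 4, 5 or 6 kept for the male alone, so that no array was shared, 967 of 978, 459 of 462 and 11 of 11 genes went the same way, but sex stays open, as the bound set before overlooked that all of this rests on 1 male Rptor cKO array. Scaling between arrays stays open for the share of lower genes, which went from 62.1% to 63.1% with quantile normalization and to 75.7% with array medians subtracted, a move of 13.6 percentage points. The 6 arrays can be divided in 10 ways into 3 and 3, too few for a share under 0.05, and the real division gave 2886 genes and the highest other 0, so 1 of 10 was as large.

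The lower lysosomal genes, with a median of -0.24, were weighed against sex, a lower share of epidermal RNA and fewer differentiated cells. A lower epidermal share stays open. The basal layer genes did not fall, with a median of 0.41 (95% bootstrap interval 0.26 to 0.60). They cannot decide it, since a larger share of basal cells among the keratinocytes could raise them despite a lower epidermal share. Sex stays open, since the male arrays alone gave -0.27 (-0.34 to -0.20) with 1 Rptor cKO array, too few for the bound set before. Fewer differentiated keratinocytes stays open too and may account for part of the shift: the slope of lysosomal on differentiation genes within groups gave 0.484 of the mean shift of 184 lysosomal genes, -0.36, with a 95% interval from -0.215 to 1.18. A direct effect of Raptor loss on lysosomal genes therefore cannot be told apart from a change in cell state with these arrays. Of the 10 divisions 1 gave as large a shift (0.24 in size, highest other 0.18), and 1 as many lists by camera with the preset correlation (33, highest other 28), which is too few divisions for a share under 0.05.

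The higher fibroblast genes were weighed against dermal tissue left on the Rptor cKO sheets and against sex. Sex stays open, since the male arrays alone, with a median of 0.77 (95% bootstrap interval 0.46 to 0.91), hold 1 Rptor cKO array, too few for the bound set before. Dermal carry-over stays open too: 30 bright markers of other dermal cell types had a median of 0.17 (0.12 to 0.38) with 25 of them higher, against 0.53 for 19 bright fibroblast genes. Keratinocytes can express some of the fibroblast list, such as Fn1 and Sparc, so a change of expression within the epidermis could also add to it, which was not tested.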

How the results depend on the processing

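The alternatives with embryo sex as a term, with the male arrays alone and without X and Y genes were chosen after the sexes were seen, and the others were planned. No paired analysis was possible because the replicate numbers 1 to 3 of Rptor cKO and 4 to 6 of wild type are not shared. The planned sex covariate, meant for groups that both hold both sexes, was not run as such because all wild-type embryos were male.

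The count of changed genes, 2886 as reported, was 2428 to 2929 under other scaling, filters, probe set rules, array weights and trended moderation and without X and Y genes. It was 8 without variance moderation, with 5783 genes at an unadjusted p under 0.05, since 4 residual degrees of freedom then carry each gene alone. It was 643 with sex as a term and 867 with the male arrays, which leave 1 Rptor cKO array, assumed to vary like the wild type. With 1 array left out the count ran from 900 (without Rptor cKO array 2) to 2444 (without Rptor cKO array 3), and 891 of the 900 were among the 2886. Fewer arrays lower the power, and any further cause was not tested.

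Rptor ran from -0.53 to -0.33 under the other settings and from -0.54 to -0.30 with 1 array left out, and never passed the threshold (adjusted p 0.0775 to 0.524). The lysosomal median ran from -0.31 with array medians subtracted to -0.19 with hydrolases and membrane proteins alone, and from -0.30 to -0.22 with 1 array left out. The lysosome list lost its call (median -0.24) with an estimated correlation, adjusted p = 0.206, and kept it elsewhere. Lists past the threshold, 33 as reported, numbered 29 to 37 over other settings and 31 to 34 with 1 array left out. There were 0 with an estimated correlation, 21 with fry and 35 with fgsea. The estimated correlation of the lysosome list, 0.12, lay above the preset 0.01. The p53, NRF2 and ATF4 lists lost their call although theirs, 0.0005, 0.0006 and -0.003, lay below it. Correlation within a list therefore cannot be the whole cause of the lost calls. The unadjusted camera p of those lists rose from 0.000622, 0.00289 and 0.0210 (preset correlation) to 0.0196, 0.0323 and 0.0525 (estimated correlation). With an estimated correlation camera uses the residual degrees of freedom of the gene fits, and with a preset correlation far more. Few arrays leave few of these, which raises p at any correlation. The share of each in the lost calls was not tested, nor were other causes. Camera moderates variances itself, so the fit without moderation did not test the lists. The FoxO target list turned from a median of -0.038 to 0.042 without wild-type array 5, within a range of -0.17 to 0.042 with 1 array left out, and the cause was not tested.

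Of 212 named genes besides Rptor, 26 lost their call with array medians subtracted, 12 with quantile normalization, 20 with trended robust moderation, 91 without Rptor cKO array 2, 94 with the male arrays, 116 with sex as a term and 200 without variance moderation, and none changed direction past the threshold.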

Other observations

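The tests of Etv4, Spry2, Spry4 and Dusp6 below were chosen after their values were seen, and those of the gene families and of 5 further ERK output genes were set before.

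Grouping genes by the stem of their symbol gave 474 families of 6 or more members among 14572 genes. By Fisher's exact test with Benjamini-Hochberg adjustment, 8 families held an excess of genes lower in Rptor cKO and 1, Mcm, an excess of higher genes. In the Skint family, 10 of 11 genes fell, with a median of -2.20 (adjusted p = 3.15e-07). In the Elovl family of fatty acid elongases 6 of 7 fell (median -1.59), in the Lce family of late envelope proteins 10 of 20 (median -1.65), and in the Aldh family of aldehyde dehydrogenases 9 of 20, with 1 higher. In the membrane traffic families Rab and Chmp (of the ESCRT-III complex), 20 of 68 and 6 of 10 genes fell, and in the Cstdc family 5 of 7. The Atp stem, which joins V-ATPase subunits, ATP synthase genes, ion pumps and flippases, held 18 lower and 3 higher of 85. In the Mcm family 5 of 9 rose (median 0.44). Skint, Lce and Cstdc genes are close paralogs whose probes may bind each other's RNA, so that their members are not independent, and a stem can join unrelated genes, so the count of 8 families is a description of these arrays.

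Stress programmes were lower or mixed. Of 24 p53 and apoptosis genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), with Trp53inp1 (-1.48, SE 0.24) and Btg2 (-1.18, SE 0.12) lower, and Plk2 higher by 1.01 (SE 0.14). Of 21 unfolded protein response genes 5 fell (5 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), among them Herpud1 (-0.97, SE 0.16) and Xbp1 (-0.79, SE 0.15). Of 19 NRF2 genes 3 fell (5 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), led by Cbr3 (-1.01, SE 0.10). Of 50 oxidative phosphorylation genes 6 fell, and 6 adjusted over the list alone, with a median of -0.11 (-0.033 without Rptor cKO array 1) and adjusted p = 0.402 with an estimated correlation. Of 30 interferon genes 3 fell, Stat2, H2-K1 and H2-D1 (-0.82, -0.46 and -0.40), with adjusted p = 0.419 with an estimated correlation. Immediate early and heat shock genes split, with Egr1 (1.04, SE 0.19) and Myc (0.76, SE 0.16) higher and 4 of 20 lower, led by Hspa1a (-1.69, SE 0.31) and Dusp1 (-1.68, SE 0.38), and camera did not call the list (adjusted p = 0.125). Without Rptor cKO array 2 the lower genes numbered 3 of the p53 list, 1 of the unfolded protein response, 1 of NRF2, 0 of oxidative phosphorylation and 0 of interferon, and of the immediate early list 0 rose and 2 fell.

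Among the other cell types, 2 of 17 melanocyte genes rose, Slc24a5 (0.62, SE 0.12) and Kit (0.63, SE 0.14), and Rab38 fell (-0.71, SE 0.14), with adjusted p = 0.532 with an estimated correlation. Of 11 mast cell genes 2 rose, Kit and Tpsb2 (0.77, SE 0.19), with a median of 0.49 (6 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.0696). Without Rptor cKO array 3, 5 mast cell genes rose. Of 13 Merkel cell genes 2 fell, Atoh1 (-0.68, SE 0.10) and Chga (-1.69, SE 0.30), and Krt18 rose (0.43, SE 0.088; camera adjusted p = 0.323 for the list). Of 18 lymphoid genes 2 fell, Ptprc (measured -0.57, SE 0.11) and Cd3g (-0.51, SE 0.11), with adjusted p = 0.333 with an estimated correlation. Ptprc lay under the negative control median on all 3 Rptor cKO arrays, and its fall was at least 1.05-fold. The simple epithelial list of 10 genes held 2 rises and the fall of Krt23 (-2.60, SE 0.44; camera adjusted p = 0.183). The erythroid (0.222), nerve and Schwann cell (0.584), adipocyte (0.261) and MiT/TFE (0.991) lists were not called by camera at these adjusted p, with 0, 1, 1 and 0 members past the threshold. Without Rptor cKO array 2, none of the melanocyte, mast cell, lymphoid and simple epithelial genes passed, and 1 Merkel cell gene was lower.

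A hypothesis from the rises of Dusp6, Spry4, Spry2 and Etv4 was that ERK pathway output as a whole was higher in Rptor cKO. It was tested on the 5 other measured members of a published ERK output list that had not been looked at. All 5 read higher, where at least 4 were predicted, but only 1 passed, Etv5 (1.34, SE 0.13, adjusted p = 0.00156), while Phlda1, Dusp4, Epha2 and Epha4 differed by 0.26, 0.044, 0.18 and 0.34 with adjusted p from 0.181 to 0.912. The prediction of at least 3 past the threshold was not met. The count of 1 also lay within the bound set before as speaking against the hypothesis. By that bound the 5 genes did not bear the hypothesis out, but all 5 read higher, so they do not settle it. The power for changes of this size is not known, since the simulated arrays held fewer changed genes than were called on the real ones.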
